A study of Gallus gallus with 28 samples.

How the data were processed

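Expression was measured with Affymetrix chicken arrays in 28 samples of 4 cell lines. Per the labels' protocols, stimulated and unstimulated cells were grown alike after a start in serum-free medium, total RNA was taken with a column kit, and biotin-labelled cRNA was made by the manufacturer's standard protocol. Each array held a pool of 10 repeated experiments, per the series description. The values were deposited as log2 signal per probe set, made by RMA per the submitters' processing notes. As a method, RMA corrects background, brings arrays to 1 distribution and summarises the probes of a set. Its version, and whether all 28 arrays were processed together, are not given in the sources used here. The median of an array's values lay between 4.37 and 4.50 log2. No image or probe-level data were reprocessed.

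Of 38535 probe sets, 153 control and reporter probe sets were left out and 38382 were tested. Gene symbols came from the platform table, with 27178 probe sets of 1 symbol, 177 of several and 11180 of none. They covered 13009 genes. A reference gene table was used for names only, where 26863 probe sets had an entry and 0 symbols changed. A gene with several probe sets was represented by the brightest over all arrays. Levels under 3.98 log2 lie near background, and a difference from such a level is a lower bound. Of 212 named calls 29 had 1 group there.

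Samples were grouped by title, because the description or source name of 5 arrays disagreed with it (2 of B7.10 and 3 of B41-13 and B46-5). DT40 and B7.10 at 6 h unstimulated, 24 h unstimulated and 6 h stimulated formed 6 groups of 3 arrays. They were fitted together with limma 3.58.1 in R 4.3.3 as group means (12 residual degrees of freedom) with moderated variances. The 16 arrays of serum batch 1 were fitted as line plus condition, without interaction (9 residual degrees of freedom), since each of their groups had 1 array. An effect of a line is therefore tested against the spread of line differences over conditions. Serum batches were compared by an F test over the 6 groups. A call is a Benjamini-Hochberg adjusted p under 0.05 over all tested probe sets, and every adjusted p of a gene comes from limma unless another tool is named. Pandas 2.3.3 and matplotlib 3.10.9 under Python 3.11.15 prepared the tables and figures.

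The number of the serum batch is the replicate number, and the labels describe a batch of serum shared by the arrays of 1 number, so the numbers pair the samples. Deviations from group means correlated with a median of 0.122 over 45 pairs of arrays from the same batch (range -0.0530 to 0.446) and of -0.06 over 90 pairs from different batches (range -0.336 to 0.280). The fit with the serum batch as a block (10 residual degrees of freedom) was run beside it.

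A set of 28 gene lists with 887 measured genes was written from general knowledge and tested with camera, a test of a list against all other genes, at a preset inter-gene correlation of 0.01. The adjusted p of a list covers the 28 lists of its comparison. As alternatives the correlation was estimated from the residuals, and fry was run, which tests whether the members change at all without reference to other genes. Members were also counted with the adjustment over the list alone. List entries were matched through synonyms of the platform table for 48 entries. That matching was widened after list values had been seen, and some aliases of the table name another gene than the one intended, such as SH2D6 for BLNK.

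Genes were named by a rule. BTK was always named. For the main comparisons the rule took up to 8 genes each way with the largest change (10 for serum batches, and 3 each way for further comparisons). They had 1 symbol, a call, and the same direction in every batch, condition or line. From each list it took up to 3 members each way with the smallest adjusted p, or 2 where none passed. Values of a second probe set, genes named for a change in the block fit or between lines at 2 h, and genes of the kinase contrast were chosen after their values were seen.

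For the return towards DT40, probe sets were chosen from the 12 arrays of serum batches 2 and 3 by adjusted p under 0.05 and at least 2-fold, and the slope through the origin was taken per condition in serum batch 1. Chosen before the data were examined were the groups, tests, lists, naming rule and these alternatives: the block, leaving out the 40% dimmest probe sets (mean under 3.98 log2), cyclic loess between arrays, moderation with trend and robust settings, only the arrays compared, and leaving out each array or group. Added later were the fits without the disputed arrays, also with the block, the fits without both 24 h arrays of serum batch 3, and the contrast of lines with and without an intact kinase.

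On simulated data with known changes, the mean difference of B7.10 from DT40 recovered 95.5% of changes of 0.5 log2 and 100% of larger ones, with 7 false calls among 38182 unchanged probe sets. For the 6 h stimulation in DT40 it was 50.7%, 89.6% and 100% at 0.5, 1 and 2 log2, and in B7.10 52.2%, 91.0% and 100%. For the difference in that response it was 16.4%, 76.1% and 95.5%, and for the difference in the 24 h change 14.9%, 71.6% and 98.5%. For the contrast of lines with and without an intact kinase it was 0%, 22.4% and 84.85%. The camera step called 1 list shifted by 0.3 log2 and 0 others of 28, and slopes given as 1, 0.4 and 0 were returned as 1.005, 0.406 and -0.00166. Genes were simulated independently of each other, so this step could not show how correlation between genes affects the list calls. Each simulation changed 67, 67 and 66 probe sets by 0.5, 1 and 2 log2 and held no serum batch effect. The real 6 h stimulation called 17 probe sets in DT40 and 0 in B7.10. With few large changes the adjustment is stricter, so the shares recovered may be too high for these comparisons.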

Results

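Gene expression was measured on 28 Affymetrix chicken arrays in 4 lines of DT40, a chicken B-cell lymphoma line that carries surface IgM and is widely used for gene disruption. The lines were parental DT40, the BTK knockout B7.10, and 2 lines made from the knockout: B41-13, given human BTK, and B46-5, given human BTK without kinase activity. BTK (Bruton's tyrosine kinase) is a Tec-family kinase that relays signals from the B-cell receptor. Cells were started in serum-free medium and kept with fetal calf serum. They were collected after 6 h or 24 h without stimulation, or after 2 h or 6 h with a stimulus labelled IgM (M4). M4 is known as a monoclonal antibody against chicken IgM that triggers the B-cell receptor. DT40 and B7.10 were grown in 3 batches of serum, which gave 3 arrays for each of the unstimulated 6 h, unstimulated 24 h and stimulated 6 h groups. The stimulated 2 h condition, and all conditions of B41-13 and B46-5, had 1 array each, in serum batch 1. Each array held RNA pooled from 10 repeated experiments, so a p-value for the groups of 3 arrays measures the spread between such pools. In serum batch 1, lines were tested against the spread of line differences over conditions. Conditions were tested against the spread of condition differences over lines, so these p-values measure no repeat of a pool. The labels of 5 arrays disagreed with their titles in serum batch, time, stimulation or line, and the title was used. The number of arrays limits the precision of every value, and gene positions were not analysed here.

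BTK itself was read by 1 chicken probe set. Its log2 level was 9.91 ± 0.35 (SD, n = 10 arrays) in DT40 and 4.99 ± 0.18 (SD, n = 10 arrays) in B7.10. The fitted difference of B7.10 from DT40 was -4.91 ± 0.09 log2 (SE, 3 arrays in each of 6 groups; limma, Benjamini-Hochberg adjusted p = 1.79e-17), which is 30.1-fold. It was -4.70, -5.10 and -4.94 in serum batches 1, 2 and 3. B41-13 stood at 5.84 ± 0.16 (SD, n = 4 arrays) and B46-5 at 5.25 ± 0.10 (SD, n = 4 arrays). BTK was 0.71 ± 0.09 log2 higher in B41-13 than in B7.10 (adjusted p = 2.13e-05), while B46-5 differed from B7.10 by 0.12 ± 0.09 (adjusted p = 0.577). Both added constructs are human, and whether the chicken probe set reads them is not given in the sources used here.

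**Figure D1:**
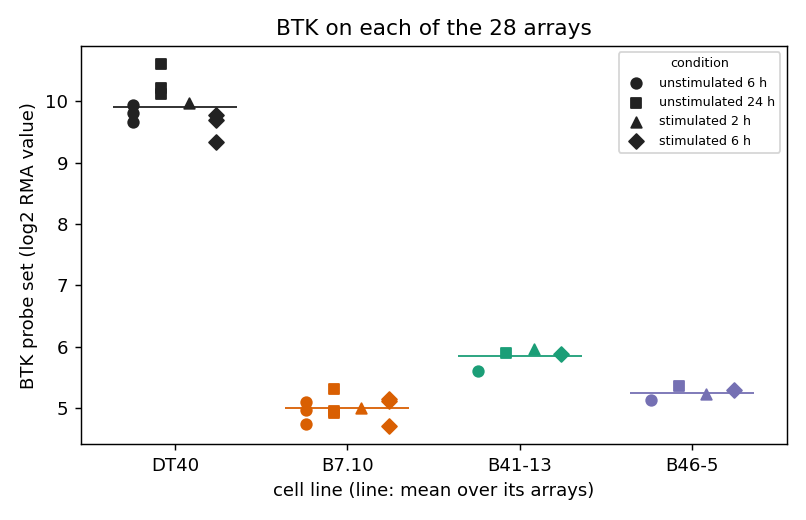
Log2 level of the BTK probe set (vertical axis) on each of the 28 arrays, by cell line (horizontal axis), with one marker shape per condition and a horizontal line at the mean of the arrays of a line. DT40 arrays lay between 9.34 and 10.61, and those of the other lines reached at most 5.97.

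The comparison of B7.10 with DT40 asked how expression differs between cells without and with BTK. The RNA-binding protein gene IGF2BP3 was 5.85 ± 0.29 log2 higher in B7.10 (SE, 3 arrays in each of 6 groups; limma, Benjamini-Hochberg adjusted p = 3.04e-11), a 57.6-fold difference. The interleukin receptor subunit IL13RA1 was higher by 4.24 ± 0.10, CMYA5 by 3.34 ± 0.17, the membrane protein PROM1 by 3.16 ± 0.25 and the p38-type kinase MAPK11 by 2.61 ± 0.10. Lower in B7.10 were the carbonic anhydrase CA3B at -5.59 ± 0.50, PINLYP at -5.23 ± 0.07, the receptor phosphatase PTPRG at -4.45 ± 0.33, the endoplasmic reticulum protein RCN1 at -4.37 ± 0.13 and the amyloid precursor APP at -4.20 ± 0.28. IL13RA1 and PROM1 in DT40, and PINLYP and PTPRG in B7.10, lay under 3.98 log2, near background, so these differences are lower bounds. The size depended on the serum batch for some of them. For IGF2BP3 the difference was 4.70, 6.61 and 6.23 in serum batches 1, 2 and 3. For CA3B it was -6.89, -2.84 and -7.03, and for APP it was -4.77, -2.72 and -5.11. CMYA5 rests on 1 of its 2 probe sets, since the other differed by 0.16.

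Genes of DNA replication were higher in B7.10 as a group. Of 48 S-phase genes, 19 were higher and 2 lower (25 and 2 adjusted over the list alone), with BRCA2 at 0.69 ± 0.07 and RFC5 at 0.44 ± 0.05. The list differed from other genes at adjusted p = 6.66e-05 (camera), and adjusted p = 0.561 with an estimated correlation. The B-cell identity list was also higher (camera adjusted p = 0.000169, and adjusted p = 0.558 with an estimated correlation), with 14 of 39 genes higher and 2 lower (16 and 2 adjusted over the list alone). Its members did not move as one. IKZF3 was higher by 0.86 ± 0.08, BCL11A by 0.73 ± 0.08 and CD200 by 1.03 ± 0.09, whereas the lymphoid transcription factors IKZF1 and EBF1 were lower at -1.17 ± 0.12 and -0.62 ± 0.07.

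Genes of the secretory and stress programmes were lower in B7.10. In the endoplasmic reticulum (ER) stress list 12 of 27 genes were lower and 1 higher (14 and 1 adjusted over the list alone; camera adjusted p = 6.66e-05). HERPUD1 stood at -0.55 ± 0.07, DERL3 at -0.45 ± 0.05 and the protein disulfide isomerase gene PDIA4 at -0.42 ± 0.06. Of 11 plasma-cell genes, 4 were lower (6 adjusted over the list alone; camera adjusted p = 0.013), among them ELL2 at -1.17 ± 0.09 and IRF4 at -0.70 ± 0.09. Of 31 genes of the ATF4 amino-acid response, 10 were lower (12 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0205), including PSAT1 at -1.41 ± 0.17 and ALDH1L2 at -0.95 ± 0.20 (near background in B7.10). Of 38 immediate-early and activation genes, 12 were lower and 1 higher (14 and 2 adjusted over the list alone; camera adjusted p = 0.0205), with DUSP5 at -1.27 ± 0.09, KLF2 at -0.98 ± 0.09 and KLF6 at -0.82 ± 0.09. These 4 lists had adjusted p = 0.558, 0.558, 0.657 and 0.558 with an estimated correlation.

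The other 22 lists did not pass camera (adjusted p from 0.183 to 0.865). Their members included 58 higher and 89 lower genes, against 68 and 105 adjusted over the list alone. Of 45 components of B-cell receptor signalling, 12 were higher, such as the kinase PRKCB at 1.20 ± 0.08 and the adaptor BANK1 at 0.83 ± 0.11. In the same list 8 were lower, such as PAG1 at -1.17 ± 0.12 and SH3BP5 at -0.51 ± 0.05. The NF-kB list had 3 higher genes, among them NFKBIZ at 0.97 ± 0.07, and 7 lower, among them NFKB1 at -0.56 ± 0.08. The calcium and NFAT list had 2 higher, including CAMKK2 at 1.89 ± 0.11 on 1 of its 2 probe sets, and 2 lower. Of the p53 and apoptosis genes 6 were higher and 7 lower, with GADD45A at 1.07 ± 0.07 and the survival gene BCL2 at -1.76 ± 0.15. The integrin and adhesion list had 3 higher, with ITGA4 at 1.46 ± 0.15 (near background in DT40), and 4 lower, with CD44 at -1.33 ± 0.10 and ITGAV at -1.37 ± 0.13. Cytokine and chemokine receptors had 6 members each way, CCR6 at 1.76 ± 0.15 among the higher (near background in DT40). The interferon list had 3 higher, SOCS1 at 1.35 ± 0.12 among them, and 2 lower. The hypoxia list had 2 higher and 8 lower, with the oxygen sensor EGLN1 at -1.67 ± 0.12.

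Among metabolic and housekeeping lists, fatty-acid synthesis had 1 higher and 6 lower genes, glycolysis 2 and 6, cholesterol synthesis and uptake 3 and 4, and oxidative phosphorylation 1 and 8. Ribosome biogenesis had 2 higher and 8 lower, the G2/M list 6 and 3, and the histones 2 and 1. Of the heat-shock genes 4 were lower, and of the ribosomal proteins 2. Markers of other cell types were few among the calls. T-cell markers had 1 higher, myeloid markers 3 higher and 1 lower (the NADPH oxidase subunit CYBB at -3.16 ± 0.36), and markers of erythroid cells and thrombocytes 1 lower. Fibroblast markers had 1 lower (BGN at -3.02 ± 0.16), and 0 of 18 epithelial markers passed limma (2 at an unadjusted p under 0.05). The G2/M list passed with cyclic loess (camera adjusted p = 0.0329, against 0.386). The median or mean change opposed the direction of the test in the receptor signalling, NF-kB, G2/M, histone, p53, cytokine receptor, integrin, myeloid and fibroblast lists.

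In all, 5157 of 38382 probe sets differed between B7.10 and DT40 as the mean over 3 conditions, 2002 higher and 3155 lower, and 482 of them by at least 2-fold. Within single conditions 1854 differed at 6 h without stimulation (633 higher, 1221 lower), 1705 at 24 h (489 higher, 1216 lower) and 2071 at 6 h with stimulation (952 higher, 1119 lower). The stimulated count and its split rest in part on 2 of 3 B7.10 arrays with disputed labels. With cyclic loess the 24 h split was 700 higher and 1051 lower. All 870 probe sets called in each of the 3 conditions had the same direction, where independent lists would share 1.33. Without serum batch 1 or 3 the mean gave 3083 and 3148. At 6 h unstimulated the count without the DT40 array of serum batch 1 or 3 was 1226 and 1146, and without the B7.10 array of those batches 1230 and 1099. At 24 h it was 968 without the B7.10 array of serum batch 3, and with stimulation it was 1304 and 1261 without the B7.10 array of serum batch 1 or 3. B7.10 was 1 line, so other differences between the lines and the loss of BTK were not separable here.

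Stimulation for 6 h was compared with 6 h without stimulation to ask which genes respond to the receptor, and whether the response needs BTK. In DT40 the membrane-associated protein gene BASP1 rose by 2.28 ± 0.20 log2 (SE, n = 3 arrays per group; limma, Benjamini-Hochberg adjusted p = 4.28e-05), from a level of 7.28 ± 0.39 to 9.56 ± 0.45 (SD). The cytokine IL18 rose by 1.77 ± 0.30, K123 by 1.89 ± 0.30 from near background, the surface peptidase MME by 1.50 ± 0.19 and the adaptor GRAPL by 1.38 ± 0.15. LGALS1A rose by 1.26 ± 0.22, HAVCR1 by 1.10 ± 0.18 and PI15 by 1.09 ± 0.16. All 17 called probe sets rose, and 2726 had an unadjusted p under 0.05 where chance gives 1919. The second probe set of IL18 changed by 1.05, those of MME by 0.56 and 0.77, those of HAVCR1 by 0.08 and 1.27, and that of GRAPL by -0.17, none past the test.

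No gene list passed in DT40 (camera, lowest adjusted p = 0.265; 2 of 28 with an unadjusted p under 0.05). CD83, an NF-kB target and activation marker, changed by 1.07 ± 0.28 (adjusted p = 0.377), the B-cell gene CD74 by 0.63 ± 0.15 (adjusted p = 0.268) and PRKCB by -0.62 ± 0.15 (adjusted p = 0.252). With the serum batch as a block the DT40 count was 41, with 40 higher and 1 lower. Without the unstimulated array of serum batch 1, 2 or 3 it was 10, 11 and 5, and without the stimulated array 7, 7 and 38.

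In B7.10 limma called 0 probe sets at 6 h of stimulation, while 6419 had an unadjusted p under 0.05 where chance gives 1919. With the serum batch as a block 616 were called, 260 higher and 356 lower. In that paired fit BCL2 rose by 0.81 (adjusted p = 0.0283), the checkpoint gene CLSPN by 0.56 (adjusted p = 0.0348) and KLF2 by 0.50 (adjusted p = 0.0388). The interleukin receptor IL7R, near background in both groups, changed by -0.63 (adjusted p = 0.0168), the matrix gene FN1 by -0.78 (adjusted p = 0.0254), the collagen gene COL1A2 by -0.49 (adjusted p = 0.0315) and TP63 by -0.35 (adjusted p = 0.0435). Without the block these 7 genes had adjusted p from 0.0656 to 0.139. Except for KLF2, which has 1 probe set, each rests on 1 probe set of several, and no other passed in the block fit (lowest adjusted p = 0.074, for CLSPN). The others changed by 0.01 and 0.15 for BCL2, 0.46 for CLSPN, -0.08 to 0.03 for IL7R, -0.29 to 0.08 for FN1, -0.36 to 0.10 for COL1A2 and -0.10 for TP63. Of the 3 stimulated B7.10 arrays, 2 have disputed labels, 1 described as unstimulated and 1 as serum batch 6 in place of 2. Without them the block fit, with 1 stimulated array left, called 0 probe sets, while FN1 changed by -0.87, BCL2 by 0.70 and KLF2 by 0.58.

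The B-cell receptor signalling list shifted up in B7.10 (camera adjusted p = 0.00916, median 0.15, and adjusted p = 0.72 with an estimated correlation), though 0 of its 45 members passed limma singly, also adjusted over the list alone (6 at an unadjusted p under 0.05). Its member IBTK, an inhibitor of BTK, changed by 0.44 ± 0.12 (adjusted p = 0.107). S-phase genes shifted up (camera adjusted p = 0.0433, median 0.05, and adjusted p = 0.794 with an estimated correlation), with 0 of 48 called by limma (4 at an unadjusted p under 0.05) and 1 higher adjusted over the list alone. Markers of fibroblasts and of epithelial cells shifted down (camera adjusted p = 0.000487 and 0.0069, medians -0.18 and -0.14), with 0 called by limma in either (9 of 25 and 5 of 18 at an unadjusted p under 0.05) and 4 and 2 lower adjusted over the list alone. Their adjusted p with an estimated correlation were 0.0534 and 0.485. The ER stress list passed only with the block (camera adjusted p = 0.044, against 0.0503). With cyclic loess the receptor signalling, S-phase and epithelial lists no longer passed (adjusted p = 0.173, 0.706 and 0.192), and 1 probe set was called. Leaving out the unstimulated B7.10 array of serum batch 1 gave 74 calls and the stimulated array of serum batch 2 gave 1.

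The test of the difference in response between the lines called 1 probe set, which reads BASP1. Its response differed by -2.21 ± 0.29 log2 in B7.10 (SE, n = 3 arrays per group; limma, Benjamini-Hochberg adjusted p = 0.0141), with -2.32, -2.90 and -1.41 in serum batches 1, 2 and 3. In B7.10 BASP1 stood at 5.36 ± 0.14 without and 5.44 ± 0.17 with stimulation (SD). With the block 2 probe sets were called. The count was 12 without the stimulated DT40 array of serum batch 3, and 2 without the unstimulated B7.10 array of serum batch 3 or the stimulated B7.10 array of serum batch 2. It was 0 without the stimulated DT40 array or the unstimulated B7.10 array of serum batch 1. Leaving out the stimulated B7.10 array of serum batch 1 or 3 also gave 0. When all arrays were used 1630 probe sets had an unadjusted p under 0.05 (limma), fewer than the 1919 that chance gives.

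The 17 probe sets that rose in DT40 had a median change of 1.23 there and of 0.03 in B7.10, where 0 of the 17 mean changes exceeded 0.5 log2. In the single pair of arrays of B41-13 the median was 0.99, with 13 of 17 above 0.5. In B46-5 it was 0.06, with 1 of 17 above 0.5. IL18 changed by 2.02 in B41-13 and by -0.04 in B46-5, MME by 1.62 and 0.05, HAVCR1 by 1.07 and -0.13. BASP1 rose in both lines on its brightest probe set, by 1.47 and 0.93, and changed by 1.20 and -0.05 on the other. K123 changed by 1.02 and 0.48. PI15 changed by 0.17 and 0.23 in these lines. The probe sets were chosen for their rise in DT40, so the DT40 median is no independent measure, and the values of B41-13 and B46-5 have no replicate. The source name of the stimulated 6 h array of B41-13 says B46-5 and 2 h, and that of B46-5 says 2 h, so the labels dispute line and time. Over the most variable probe sets 0 of 16 arrays of serum batch 1 lay closest to another line. Median changes of the cholesterol list were 0.15 in B41-13 and 0.06 in B46-5 for these arrays, against 1.33 and 0.49 for those titled 2 h. These values argue against another line or 2 h for the 2 arrays.

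**Figure D2:**
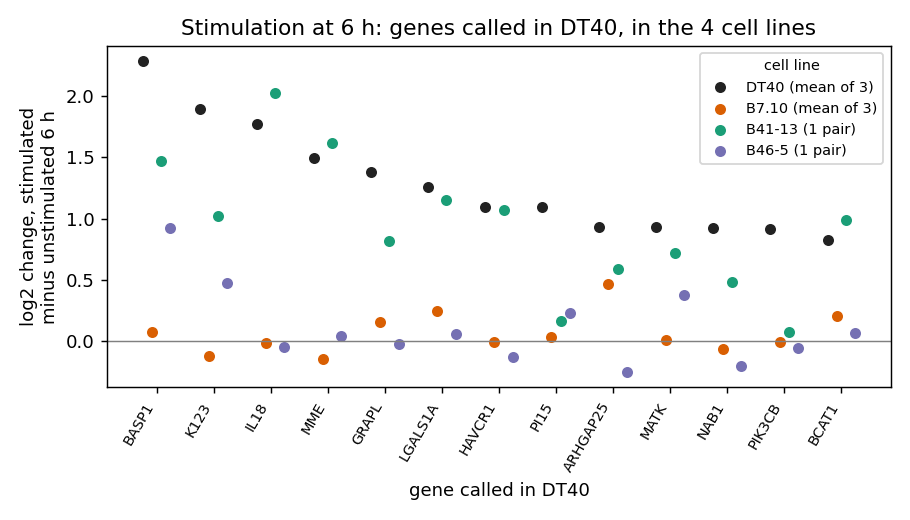
Log2 change from 6 h unstimulated to 6 h stimulated (vertical axis) for the genes called in DT40 (horizontal axis, 1 probe set per gene), with 1 point per cell line. DT40 and B7.10 points are means of 3 pairs and B41-13 and B46-5 points are single pairs, with medians over all 17 probe sets of 1.23, 0.03, 0.99 and 0.06.

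Unstimulated cells at 24 h were compared with those at 6 h. In DT40 genes of sterol synthesis rose, with the sterol dehydrogenase NSDHL at 1.52 ± 0.14 log2 (SE, n = 3 arrays per group; limma, Benjamini-Hochberg adjusted p = 1.99e-05), the squalene synthase FDFT1 at 1.01 ± 0.15, the sterol sensor INSIG1 at 0.95 ± 0.12 and IDI2 at 0.88 ± 0.13. The acyl-CoA synthetase gene ACSBG2 rose by 1.01 ± 0.13, CCNA1 by 0.89 ± 0.12 and, on 1 of its 3 probe sets, ACACA by 0.70 ± 0.14. MAT1A fell by 2.04 ± 0.21, OSTN by 1.75 ± 0.16 to near background, the haem oxygenase HMOX1 by 1.47 ± 0.24, the receptor F2RL1 by 1.27 ± 0.24, TMEM47 by 1.24 ± 0.19 and the haem-responsive repressor BACH1 by 1.22 ± 0.22. LDHA fell by 0.72 ± 0.13 and HSPA2 by 0.78 ± 0.14. UCHL1, GPR183 and ELL2 fell by 1.78 ± 0.23, 1.08 ± 0.21 and 0.76 ± 0.16 on 1 probe set each, their other probe sets not passing, and UCHL1 fell to near background.

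Of 22 genes of cholesterol synthesis and uptake 7 rose in DT40 (10, with 1 lower, adjusted over the list alone; camera adjusted p = 1.52e-07, and adjusted p = 0.246 with an estimated correlation). In the ER stress list DERL1 and DERL3 fell by 0.45 ± 0.09 and 0.44 ± 0.09, and the stress kinase gene EIF2AK3 rose by 0.62 ± 0.12. Adjusted over the list alone 7 of 27 were lower and 1 higher (camera adjusted p = 1.41e-06, and adjusted p = 0.479 with an estimated correlation). In the ATF4 list SLC7A11 fell by 0.95 ± 0.16, and 6 of 31 were lower adjusted over the list alone (camera adjusted p = 0.00334, and adjusted p = 0.859 with an estimated correlation). Ribosome biogenesis shifted up with a median of 0.08 and ribosomal proteins down with a median of -0.04, with 0 members called by limma in either list, also adjusted over the list alone, and 10 of 60 and 2 of 66 at an unadjusted p under 0.05 (camera adjusted p = 0.00629 and 0.036, and adjusted p = 0.924 for both with an estimated correlation). The ribosomal protein call ended with the block (adjusted p = 0.0541) and with cyclic loess (adjusted p = 0.113).

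In B7.10 NSDHL rose by 0.83 ± 0.14, ACSBG2 by 0.84 ± 0.13, TIPARP by 0.65 ± 0.13 and, on 1 of its 4 probe sets, STK32C by 0.79 ± 0.15. TMEM47 fell by 1.50 ± 0.19, F2RL1 by 1.33 ± 0.24, GPR137B by 1.20 ± 0.16, HSPA2 by 1.09 ± 0.14, CTSV by 1.01 ± 0.20 and, on 1 of its 4 probe sets, SERINC5 by 1.33 ± 0.18. The receptor TGFBR1 fell by 0.84 ± 0.16 in B7.10 and by 0.81 ± 0.16 in DT40. With the block DERL1, the chaperone gene HSPA5, HMOX1 and, on 1 of its 2 probe sets, PSPH also passed, at -0.45, -0.43, -0.82 and -0.96 (adjusted p = 0.0371, 0.0366, 0.0312 and 0.0466, against 0.057, 0.0954, 0.164 and 0.103). In B7.10 the cholesterol list shifted up, with 1 of 22 higher (4, with 1 lower, adjusted over the list alone; camera adjusted p = 0.00213). The ER stress list shifted down with 0 of 27 called by limma (9 at an unadjusted p under 0.05) and 6 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00203). Both had adjusted p = 0.897 with an estimated correlation. Ribosomal proteins shifted down by a median of -0.14, with 0 of 66 called by limma, also adjusted over the list alone, and 12 at an unadjusted p under 0.05 (camera adjusted p = 8.49e-07, and adjusted p = 0.918 with an estimated correlation), and with cyclic loess the adjusted p was 0.86.

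The 24 h comparison called 220 probe sets in DT40 (80 higher, 140 lower) and 89 in B7.10 (27 higher, 62 lower, or 52 and 58 with cyclic loess). Called in both lines were 38, all 38 in the same direction, where independent lists would share 0.28. With the block the counts were 554 and 270. In DT40 the count without the 6 h array of serum batch 1, 2 or 3 was 95, 132 and 79, and without the 24 h array 1341, 69 and 81. In B7.10 the same arrays gave 11, 21 and 15, and 254, 290 and 9. On principal component 2 of all arrays both 24 h arrays of serum batch 3 stood apart, at 39.7 in DT40 and 30.2 in B7.10. The other 24 h arrays of these lines lay between 6.61 and 22.3. Without both arrays of serum batch 3 the counts were 97 in DT40 and 17 in B7.10.

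Between the lines the 24 h change differed for MAT1A and OSTN. MAT1A, a methionine adenosyltransferase gene, had a change 2.09 ± 0.29 log2 higher in B7.10 (SE, n = 3 arrays per group; limma, Benjamini-Hochberg adjusted p = 0.0177) and OSTN 1.90 ± 0.23 (adjusted p = 0.00374). In DT40 MAT1A stood at 7.85 ± 0.31 at 6 h and 5.81 ± 0.41 at 24 h, whereas in B7.10 it was 3.58 ± 0.14 and 3.64 ± 0.15 (SD). OSTN stood at 5.44 ± 0.21 and 3.68 ± 0.26 in DT40 and at 3.63 ± 0.06 and 3.78 ± 0.16 in B7.10. The B7.10 levels of both genes lay under 3.98, near background, so a fall there may not have been readable and no difference in regulation follows. One of these 2 calls was lost without the 6 h array of DT40 in serum batch 3, the 6 h array of B7.10 in serum batch 1 or 3, or the 24 h array of B7.10 in serum batch 2 or 3. The ATF4 list fell less in B7.10 (median difference 0.10) and the cholesterol list rose less (median difference -0.25), both at camera adjusted p = 0.00384, and at adjusted p = 0.934 and 0.843 with an estimated correlation. No member of either passed limma (2 of 31 and 5 of 22 at an unadjusted p under 0.05, and 2327 of all probe sets where chance gives 1919), and adjusted over the list alone 1 member of each did.

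The 3 batches of serum were compared across the 6 groups of DT40 and B7.10. The batch number is also the replicate number, so serum was not separable from other differences between the replicate sets. The signalling inhibitor SPRY2 averaged 5.66, 6.78 and 5.25 log2 in serum batches 1, 2 and 3 (n = 6 arrays each; limma F test, Benjamini-Hochberg adjusted p = 0.0271). CYBB averaged 6.14, 7.25 and 5.76, and the clock-related repressor BHLHE41 rose from 6.81 in batch 1 to 8.24 in batch 2. The surface enzyme CD38 averaged 6.28, 5.02 and 5.84, the metalloproteinase MMP2 6.62, 5.39 and 6.12 and MYCN 6.14, 5.58 and 6.71. Smaller ranges were seen for SESN1 (0.70 log2), BCL2 (0.66), PRKCD (0.49), TNFAIP3 (0.44), the chemokine receptor CXCR4 (0.39) and VIM (0.37), all past the test. In total 298 probe sets differed. Pairs of batches gave 110 calls for batch 2 against 1, 177 for batch 3 against 2 and 12 for batch 3 against 1.

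Of the gene lists, G2/M genes were lower in serum batch 3 than in batch 1 (camera adjusted p = 8.69e-06, median -0.10), as were ER stress genes (adjusted p = 0.000472, median -0.11), receptor signalling components (adjusted p = 0.000789, median -0.12), S-phase genes (adjusted p = 0.00175, median -0.08), p53 and apoptosis genes (adjusted p = 0.0107, median -0.08) and B-cell identity genes (adjusted p = 0.0289, median -0.05). ATF4 genes, epithelial markers and erythroid markers were higher (adjusted p = 0.0107, 0.00616 and 0.0368; medians 0.08, 0.08 and 0.08). No member of these 9 lists passed limma over all probe sets for this pair of batches. At an unadjusted p under 0.05 they had 15, 8, 9, 15, 10, 12, 2, 3 and 2 members in the order named. Adjusted over the list alone 6 B-cell identity, 2 G2/M, 2 ER stress and 1 p53 gene were lower and 1 S-phase gene was higher, and with an estimated correlation their adjusted p lay between 0.152 and 0.603. The S-phase, B-cell identity, epithelial and erythroid lists no longer passed with cyclic loess (adjusted p = 0.371, 0.069, 0.201 and 0.181). Between batches 2 and 1 no list passed (camera, lowest adjusted p = 0.123; 4 with an unadjusted p under 0.05). Without one of the 6 groups the count of probe sets was 82 (DT40 at 6 h), 119 (DT40 at 24 h), 57 (B7.10 at 6 h), 87 (B7.10 at 24 h) and 102 (B7.10 stimulated).

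The lines given human BTK were compared with the knockout in serum batch 1, over 4 conditions with 1 array each. In B41-13, with an active kinase, CA3B was 4.72 ± 0.16 log2 higher than in B7.10 (SE, n = 4 arrays per line; limma, Benjamini-Hochberg adjusted p = 2.34e-12), a 26.3-fold difference. BASP1 was higher by 4.39 ± 0.26, CA12 by 3.95 ± 0.18, BHLHE41 by 3.79 ± 0.24, CYBB by 3.60 ± 0.20, DCX by 3.53 ± 0.18, IL18 by 3.49 ± 0.38, the class II gene BLB1 by 3.41 ± 0.11 and, on 1 of its 2 probe sets, PALLD by 4.52 ± 0.15. IL13RA1 was lower at -4.52 ± 0.19, PROM1 at -3.65 ± 0.11, the lipoprotein receptor VLDLR at -2.29 ± 0.09 and, on 1 probe set each, CMYA5 at -3.09 ± 0.16 and ITGA4 at -2.34 ± 0.17. CA3B, BASP1, IL13RA1 and PROM1 thus lay on the DT40 side of B7.10. CA3B, PALLD, CA12 and DCX in B7.10, and IL13RA1, PROM1, VLDLR and ITGA4 in B41-13, lay under 3.98 log2, near background, so these differences are lower bounds.

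Of 38 immediate-early and activation genes 14 were higher in B41-13 than in B7.10 and 3 lower (the same adjusted over the list alone; camera adjusted p = 3.92e-05), with SPRY2 at 2.76 ± 0.19 and KLF2 at 1.69 ± 0.10. SPRY2 was also higher in B46-5 than in B7.10, by 2.31, and varied between the serum batches. The NF-kB list had 6 of 31 higher and 1 lower (8 and 2 adjusted over the list alone; camera adjusted p = 0.0364), with CD83 at 2.98 ± 0.68 (near background in B7.10), TNFAIP3 at 1.98 ± 0.49 and NFKB1 at 0.98 ± 0.18. For CD83 the difference was 5.79 at 2 h of stimulation and 1.86 at 6 h without stimulation. In the ER stress list 7 of 27 were higher and 1 lower (9 and 2 adjusted over the list alone; camera adjusted p = 0.0265), HERPUD1 among them at 1.22 ± 0.24. In oxidative phosphorylation 5 of 66 were higher (5 adjusted over the list alone; camera adjusted p = 0.0265), with NDUFB7 at 0.49 ± 0.08 and, on 1 probe set, UQCRFS1 at 0.58 ± 0.07. The G2/M list had 12 of 52 lower and 1 higher (21 and 2 adjusted over the list alone; camera adjusted p = 3.92e-05), such as CDC20 at -0.56 ± 0.08, FOXM1 at -0.59 ± 0.10 and KIF15 at -0.56 ± 0.11. With an estimated correlation these lists, in the order named, had adjusted p = 0.748, 0.748, 0.748, 0.749 and 0.749, and with cyclic loess the NF-kB list had 0.114. The kinase genes PRKCB and TEC stood at -1.22 ± 0.13 and 1.09 ± 0.13.

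In B46-5, with an inactive kinase, BHLHE41 was 3.71 ± 0.24 log2 higher than in B7.10 (SE, n = 4 arrays per line; limma, Benjamini-Hochberg adjusted p = 8.06e-09), CYBB 3.52 ± 0.20, the phosphatase gene DUSP4 2.62 ± 0.16, the ETS factor ETV5 2.46 ± 0.11, SPRY2 2.31 ± 0.19, CD44 1.57 ± 0.10 and BLB1 1.56 ± 0.11. BTBD11 was lower at -4.57 ± 0.19, RGCC at -4.29 ± 0.17, MMP2 at -3.62 ± 0.23, the actin-bundling LCP1 at -3.09 ± 0.12, CD38 at -2.49 ± 0.19, IL13RA1 at -2.44 ± 0.19 and VIM at -1.75 ± 0.07. FABP5, TEC and CD81 were lower at -3.03 ± 0.11, -1.30 ± 0.13 and -1.37 ± 0.10, each on 1 probe set while the others did not pass. MMP2 and TEC lay near background in B46-5. Several of these genes also varied between cultures of DT40 and B7.10. BHLHE41, CYBB and SPRY2 averaged higher in serum batch 2 than in batch 1, and BTBD11, MMP2, CD38 and VIM lower. CD44 hardly moved, with 8.71 in batch 1 and 8.68 in batch 2. With 1 line per construct, such variation was not separable from an effect of the construct. No list passed for B46-5 against B7.10 (camera, lowest adjusted p = 0.175; 6 of 28 with an unadjusted p under 0.05).

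Compared with each other, B41-13 had 4.58 ± 0.16 log2 more CA3B than B46-5 (SE, n = 4 arrays per line; limma, Benjamini-Hochberg adjusted p = 3.15e-12) and 4.46 ± 0.26 more BASP1, with LY6E at 4.35 ± 0.11 on 1 of its 4 probe sets. CREB3L2 was lower at -3.06 ± 0.11, VLDLR at -2.80 ± 0.09 and NEDD9 at -2.71 ± 0.12. CA3B in B46-5 and VLDLR in B41-13 lay near background, so their differences are lower bounds. NF-kB and B-cell identity genes were higher in B41-13 (8 of 31 higher and 1 lower, and 10 of 39 and 3, or 9 and 1, and 12 and 4 adjusted over the list alone; camera adjusted p = 0.0122 for both). So were immediate-early genes (10 of 38 and 4 lower, 11 and 4 adjusted over the list alone) and ER stress genes (6 of 27, or 7 and 2 lower adjusted over the list alone), both at adjusted p = 0.042. G2/M genes were lower (4 of 52 and 1 higher, the same adjusted over the list alone; adjusted p = 0.0222). These 5 had adjusted p = 0.651, 0.585, 0.651, 0.651 and 0.785 with an estimated correlation, and with cyclic loess the immediate-early list had 0.0724.

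The counts were 4130 probe sets for B41-13 against B7.10 (1547 higher, 2583 lower, or 1935 and 2040 with cyclic loess), 2705 for B46-5 against B7.10 (1223 higher, 1482 lower) and 4244 for B41-13 against B46-5 (1790 higher, 2454 lower, or 2168 and 1929 with cyclic loess). Without the 3 arrays whose labels disagree (6 h stimulated in both lines and 24 h in B46-5) the last 2 were 1406 and 2190. Each construct was represented by 1 line, so other differences between the lines are part of these counts.

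Against DT40 in serum batch 1, BTK stood at -4.77 ± 0.09 in B7.10, -4.06 ± 0.09 in B41-13 and -4.65 ± 0.09 log2 in B46-5 (SE, n = 4 arrays per line; limma, Benjamini-Hochberg adjusted p = 1.87e-16, 1.43e-15 and 4.93e-16). IGF2BP3 was higher than in DT40 in all 3 lines, by 4.68 ± 0.09, 4.70 ± 0.09 and 4.26 ± 0.09. CA3B stood at -6.80 ± 0.16 in B7.10 and -6.66 ± 0.16 in B46-5. PINLYP stood at -4.40 ± 0.10 in B41-13 and -5.33 ± 0.10 in B46-5, PPDPF at -4.30 ± 0.16 in B41-13 and LCP1 at -5.51 ± 0.12 in B46-5. CA3B in B7.10 and B46-5, and PINLYP in B46-5, lay near background. S-phase genes were higher than in DT40 in each of the 3 lines (12, 11 and 13 of 48 higher and 1, 0 and 0 lower by limma; 21, 14 and 14 higher and 2, 1 and 0 lower adjusted over the list alone). Their camera adjusted p were 3.29e-05, 0.000275 and 0.000361, and adjusted p = 0.507, 0.474 and 0.448 with an estimated correlation. ATF4 genes were lower in each (10, 11 and 10 of 31 lower and 0, 1 and 0 higher; 15, 14 and 16 lower and 1, 5 and 1 higher adjusted over the list alone). Their camera adjusted p were 0.000832, 0.00643 and 0.000361, and adjusted p = 0.417, 0.474 and 0.334 with an estimated correlation. The 3 comparisons share the DT40 arrays, so these likenesses partly share chance values. They called 4173, 4929 and 4376 probe sets (1793 higher and 2380 lower, 1672 and 3257, 1806 and 2570).

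To measure how far each line lay from B7.10 towards DT40, 419 probe sets were taken that differed by at least 2-fold between B7.10 and DT40 in serum batches 2 and 3 (121 higher and 298 lower in B7.10). Their difference from B7.10 in serum batch 1 was then regressed on the difference of DT40 from B7.10 in the other batches, so that no array entered both sides. B7.10 was subtracted on both sides, so a trait of that line alone would give B41-13 and B46-5 positive slopes without a return. The slope was 1.08 ± 0.03 (SD, n = 4 conditions) for DT40 itself, 0.41 ± 0.04 for B41-13 and 0.23 ± 0.005 for B46-5. The slope of B41-13 exceeded that of B46-5 by 0.18 ± 0.04 (SD) in 4 of 4 conditions (exact two-sided sign-flip test, p = 0.125, the smallest p that 4 conditions allow). Of the 419 probe sets 250 differed between the 2 lines, 167 of them further in the direction of DT40 in B41-13 and 83 in B46-5. By distance from the DT40 level of serum batch 1, B41-13 was closer at 172 and B46-5 at 78. The probe sets are not independent replicates, and 1 line stood for each construct.

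**Figure D3:**
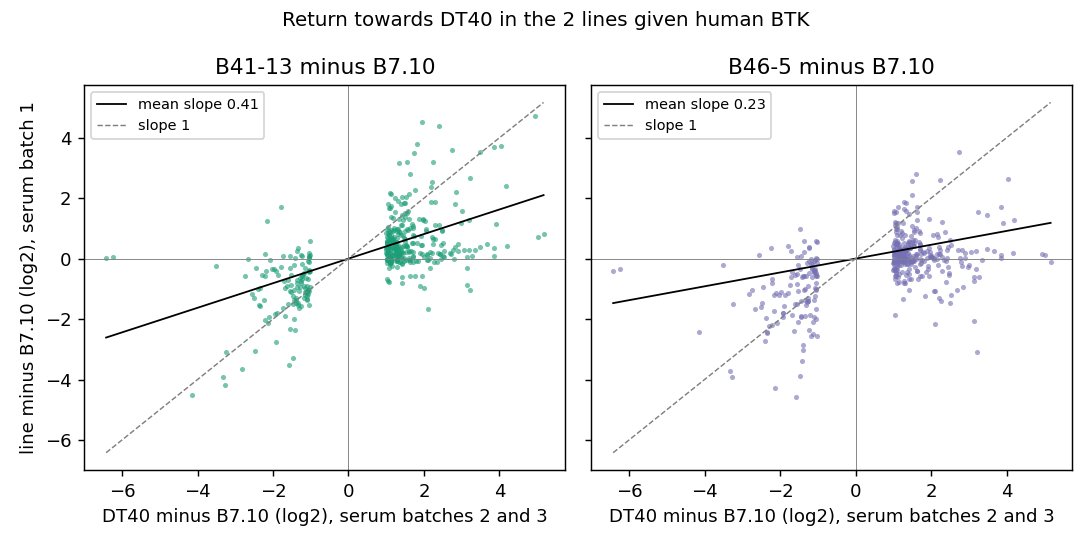
Difference from B7.10 in serum batch 1 (vertical axis, log2) against the difference of DT40 from B7.10 in serum batches 2 and 3 (horizontal axis, log2) for 419 probe sets, for B41-13 (left) and B46-5 (right). Solid lines have the mean slopes of 0.41 and 0.23, and the dashed line has slope 1.

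The stimulated 2 h arrays were compared with the unstimulated 6 h arrays over the 4 lines, to ask for early responses to the receptor. No unstimulated 2 h array was analysed here, so stimulation, the shorter culture and the serum-free start were not separable. ACSBG2 was higher at 2 h by 2.08 ± 0.10 log2 (SE, n = 4 arrays per condition; limma, Benjamini-Hochberg adjusted p = 3.31e-09), and so were the sterol genes NSDHL at 2.03 ± 0.15, LSS at 1.65 ± 0.12 and FDPS at 1.35 ± 0.09. The small GTPase gene RHOB was higher by 1.80 ± 0.13 on 1 of its 2 probe sets. HSPA2 was lower at -1.91 ± 0.13, KCNMB1 at -1.77 ± 0.15, and the mitotic genes BORA, ANLN, CENPF and KIF14 at -1.33 ± 0.12, -1.23 ± 0.15, -1.20 ± 0.20 and -1.18 ± 0.16.

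A group of activation genes had unequal changes between the lines. CD83 was higher on average by 2.65 ± 0.68 (adjusted p = 0.0224), with changes of 5.54 in DT40, 0.29 in B7.10, 4.22 in B41-13 and 0.55 in B46-5. The phosphatase gene DUSP5, which acts on ERK, averaged 2.65 ± 0.53, with 3.91, 0.18, 5.00 and 1.51 in the same order of lines. RASGEF1A averaged 2.31 ± 0.51, with 4.51, 0.15, 3.36 and 1.22. The NF-kB inhibitor TNFAIP3 averaged 1.93 ± 0.49, with 3.67, 0.45, 3.39 and 0.19. On 1 of its 2 probe sets EGR1 averaged 1.68 ± 0.43, with 3.54, 0.29, 2.41 and 0.46. CD83 and EGR1 lay near background without stimulation. Other activation genes changed in each of the 4 lines by at least 0.89, with KLF6 at 1.01, 1.29, 1.74 and 1.47, KLF2 at 0.89, 1.57, 1.66 and 1.37 and, on 1 of its 4 probe sets, ID2 at 1.97, 1.02, 1.58 and 1.11.

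**Figure D4:**
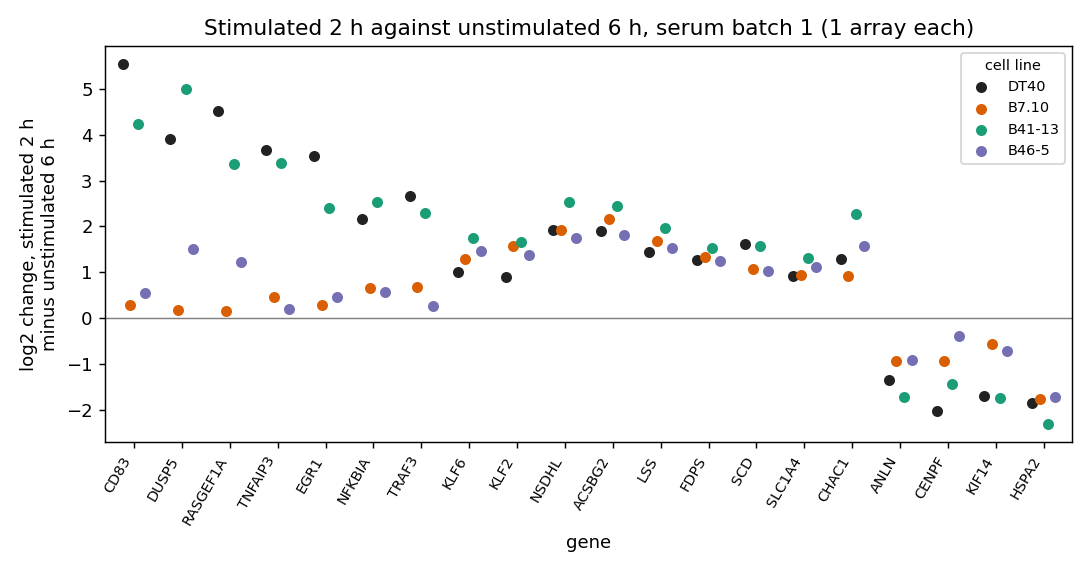
Log2 change from 6 h unstimulated to 2 h stimulated (vertical axis) in serum batch 1 for named genes (horizontal axis), with 1 point per cell line from 1 pair of arrays. CD83 changed by 5.54 in DT40 and 4.22 in B41-13 against 0.29 in B7.10 and 0.55 in B46-5, while NSDHL changed by 1.91, 1.92, 2.53 and 1.74 in DT40, B7.10, B41-13 and B46-5.

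Of 22 genes of cholesterol synthesis and uptake 16 were higher at 2 h (18 adjusted over the list alone; camera adjusted p = 1.12e-27, median 1.04, and adjusted p = 0.0159 with an estimated correlation). Of 31 ATF4 genes 14 were higher (18 adjusted over the list alone; camera adjusted p = 7.21e-17), such as CHAC1 at 1.51 ± 0.14, GPT2 at 1.35 ± 0.14 and the transporter SLC1A4 at 1.08 ± 0.08. Of 38 immediate-early genes 16 were higher (21 adjusted over the list alone; camera adjusted p = 4.86e-15). Fatty-acid synthesis had 8 of 19 higher (9, with 2 lower, adjusted over the list alone; camera adjusted p = 1.63e-06), with SCD at 1.32 ± 0.11, ELOVL5 at 0.92 ± 0.07 and ACSL3 at 0.71 ± 0.08. Cytokine and chemokine receptors had 7 of 49 higher and 2 lower (the same adjusted over the list alone; camera adjusted p = 0.00705), with TNFRSF21 at 0.69 ± 0.10. These 4 lists kept the call with an estimated correlation (adjusted p = 0.0159, 0.0492, 0.0427 and 0.0427).

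The NF-kB list had 8 of 31 higher (11 adjusted over the list alone; camera adjusted p = 0.000609), with NFKBIA at 1.48 ± 0.27, TRAF3 at 1.48 ± 0.30 and, on 1 probe set, REL at 0.75 ± 0.13. Glycolysis and hypoxia genes were each higher in 3 members (camera adjusted p = 0.00093 and 0.00171; 3 higher and 1 lower, and 3 higher adjusted over the list alone), including the glucose transporter SLC2A1 at 1.53 ± 0.16 and, on 1 probe set, the lactate transporter SLC16A3 at 1.31 ± 0.15. With an estimated correlation these 3 lists had adjusted p = 0.26, 0.204 and 0.063. The G2/M list had 23 of 52 lower (35 adjusted over the list alone; camera adjusted p = 4.86e-15), with CENPI at -0.89 ± 0.11 and NCAPG at -0.74 ± 0.10. S-phase genes had 8 of 48 lower and 2 higher (14 and 3 adjusted over the list alone; camera adjusted p = 0.002), with ORC1 at -0.89 ± 0.09 and RRM2 at -0.47 ± 0.09. Heat-shock genes had 8 of 28 lower and 1 higher (10 and 1 adjusted over the list alone; camera adjusted p = 0.00085), with CHORDC1 at -0.94 ± 0.08 and HSPA8 at -0.60 ± 0.07. With an estimated correlation these 3 had adjusted p = 0.247, 0.46 and 0.0914.

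Weaker shifts were seen upward in receptor signalling (6 of 45 higher and 3 lower, 10 and 5 adjusted over the list alone), calcium and NFAT genes (4 of 26 and 3, 4 and 4 adjusted over the list alone) and p53 and apoptosis genes (7 of 39 and 5, 10 and 6 adjusted over the list alone). Their camera adjusted p were 0.0421, 0.0326 and 0.0359, and adjusted p = 0.377 for all 3 with an estimated correlation. Oxidative phosphorylation shifted downward (2 of 66 lower, 1 adjusted over the list alone; camera adjusted p = 0.0142, and adjusted p = 0.653 with an estimated correlation). Receptor signalling, p53 and oxidative phosphorylation did not pass with cyclic loess (adjusted p = 0.0801, 0.0801 and 0.172). The survival gene MCL1 was higher by 0.74 ± 0.12 and IRF4 by 0.55 ± 0.12, and IKZF1 was lower at -0.65 ± 0.10 on 1 of its 2 probe sets. BTK changed by 0.13 ± 0.09 (adjusted p = 0.436).

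**Figure D5:**
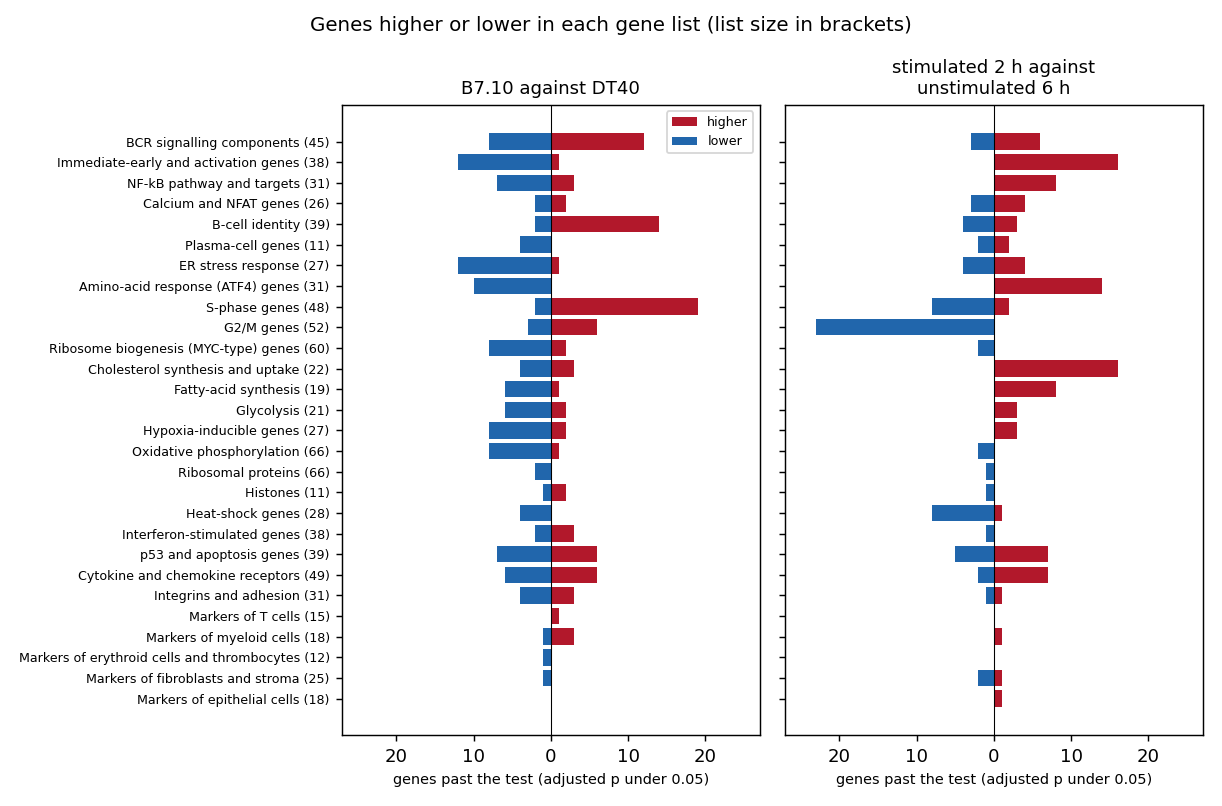
Number of genes that were higher (red, to the right) or lower (blue, to the left) at adjusted p under 0.05 in each of the 28 gene lists (vertical axis, list size in brackets), for B7.10 against DT40 (left) and 2 h stimulated against 6 h unstimulated (right). In the right panel 16 of 22 cholesterol genes were higher and 23 of 52 G2/M genes lower.

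At 2 h 3056 probe sets differed from 6 h unstimulated (1353 higher, 1703 lower, or 1798 and 1179 with cyclic loess). The count was 1754 without the unstimulated B41-13 array, 1820 without its 2 h array and 1854 without the unstimulated B46-5 array. Against 6 h of stimulation 2747 differed (797 higher, 1950 lower, or 1195 and 1399 with cyclic loess), with DUSP5, on 1 of its 2 probe sets, at 2.48 ± 0.53 log2 (SE, n = 4 arrays per condition; limma, Benjamini-Hochberg adjusted p = 0.00653), ACSBG2 at 2.00 ± 0.10 and HSPA2 at -2.17 ± 0.13. In that comparison 16 of 22 cholesterol genes and 13 of 31 ATF4 genes were higher (17 with 1 lower, and 19 with 1 lower adjusted over the list alone; camera adjusted p = 4.05e-26 and 3.29e-16, and adjusted p = 0.0189 for both with an estimated correlation). Cytokine and chemokine receptors had 4 of 49 higher and 1 lower (the same adjusted over the list alone; camera adjusted p = 0.00713, 0.0481 with an estimated correlation and 0.0571 with cyclic loess). These 3 lists and the 5 of the comparison with 6 h unstimulated are the 8 of 112 list calls that held with an estimated correlation. G2/M genes had 28 of 52 lower (36 adjusted over the list alone; camera adjusted p = 1.19e-16, and adjusted p = 0.181 with an estimated correlation). Immediate-early genes had 16 of 38 higher (19 adjusted over the list alone; camera adjusted p = 1.08e-11, and adjusted p = 0.0972 with an estimated correlation). Source names give 2 h for the stimulated 6 h arrays of B41-13 and B46-5. Without the 3 arrays with disputed labels 970 probe sets differed between 2 h and 6 h of stimulation (311 higher, 659 lower).

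By 6 h of stimulation the 4 lines of serum batch 1 together gave 5 calls against 6 h unstimulated (3 higher, 2 lower), with 1 named gene, MFGE8, at -0.58 ± 0.09 on 1 of its 2 probe sets (SE, n = 4 arrays per condition; limma, Benjamini-Hochberg adjusted p = 0.0329). No list passed (camera, lowest adjusted p = 0.0617; 7 of 28 with an unadjusted p under 0.05). The count was 0 without the unstimulated array of B7.10 or B41-13 or the stimulated array of B41-13. It was 3 without the stimulated array of DT40 or B46-5, 2 without that of B7.10 and 1 without the unstimulated array of B46-5. When all arrays were used 5244 probe sets had an unadjusted p under 0.05 (limma), where chance gives 1919.

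At 24 h unstimulated in serum batch 1 NSDHL was higher than at 6 h by 1.19 ± 0.15 log2 (SE, n = 4 arrays per condition; limma, Benjamini-Hochberg adjusted p = 0.00101), with 1.47, 0.71, 1.77 and 0.81 in DT40, B7.10, B41-13 and B46-5. TMEM47 was lower at -0.98 ± 0.15 and, on 1 probe set each, the kinase gene FYN at -0.97 ± 0.18 and PSPH at -0.97 ± 0.12. The cholesterol list had 4 of 22 higher and 1 lower (7 and 1 adjusted over the list alone; camera adjusted p = 0.00174). ER stress had 2 of 27 lower (5 adjusted over the list alone) and the ATF4 list 5 of 31 lower (8, with 1 higher, adjusted over the list alone), at camera adjusted p = 0.000521 and 0.000873. With an estimated correlation all 3 had adjusted p = 0.901. In all 361 probe sets differed (116 higher, 245 lower, or 206 and 212 with cyclic loess). Without the 6 h array of DT40, B7.10, B41-13 or B46-5 the count was 113, 104, 150 and 152, and without the 24 h array 198, 197, 183 and 232.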

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

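The splits of the arrays and the tests of array scaling were written down beforehand, while the contrast of lines by kinase and the tests of line labels, of exchanged arrays, of disputed labels, of drift of single lines, of array quality and of a response without BTK were chosen after the results were seen.

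At 2 h of stimulation some activation genes rose more in DT40 and B41-13 than in B7.10 and B46-5, while KLF2 and KLF6 rose less in DT40 than in those lines. NR4A3, an orphan nuclear receptor induced by the antigen receptor, changed by 2.44 in DT40 and 2.18 in B41-13 against -0.23 in B7.10 and 0.05 in B46-5 (difference of class means 2.40 ± 0.18 log2, SE, n = 2 lines per class; limma, Benjamini-Hochberg adjusted p = 1.12e-05). CD83 differed by 4.46 ± 0.40, TNFAIP3 by 3.20 ± 0.33, WNT9A by 2.26 ± 0.20, DUSP5 by 3.61 ± 0.45, EGR1 by 2.60 ± 0.35, NFKBIA by 1.73 ± 0.24 and MAP3K8 by 2.31 ± 0.36, while CREBRF differed by -1.21 ± 0.19, each on its brightest probe set. With trend and robust moderation DUSP5 no longer passed (adjusted p = 0.0633). Median changes of the immediate-early list were 0.69, 0.21, 0.67 and 0.13 in DT40, B7.10, B41-13 and B46-5, with 7 of 38 members called (camera adjusted p = 2.14e-19, and 0.0121 with an estimated correlation). Those of the NF-kB list were 0.30, 0.02, 0.17 and 0.00, with 8 larger and 1 smaller (adjusted p = 3.28e-13, and 0.0468). Medians of the G2/M list were -0.47, -0.13, -0.43 and -0.25, with 1 of 52 members called (adjusted p = 1.07e-11, and 0.49 with an estimated correlation). Those of the cholesterol list were 1.18, 0.95, 1.33 and 0.49, with 0 of 22 called by limma (adjusted p = 3.31e-08, and 0.24). What flagged this was a difference between groups of lines, with 101 probe sets called (76 higher, 25 lower).

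Scaling of the arrays would shrink the difference in the median immediate-early change, which was 0.51 as deposited and 0.55 with cyclic loess. A mix-up of lines would place an array nearest to another line over the 1000 most variable probe sets, and 0 of 16 arrays lay so. If the 2 h and 6 h stimulated arrays of B46-5 had been exchanged, the array titled 6 h would show the early cholesterol rise, but its median change was 0.0623 against 0.486 for the array titled 2 h. The other 2 pairings of the lines gave 1 and 0 calls in place of 101. Loss of BTK kinase activity could give this pattern, but only 3 pairings exist, each class held 2 lines with 1 line per construct, and the pattern was found and tested on the same data, so it remains a hypothesis.

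B41-13 lay further in the direction of DT40 than B46-5 over the 419 probe sets chosen in other batches, with slopes of 0.41 and 0.23. Disputed labels could have produced this, yet in the conditions with undisputed labels the slope difference was at least 0.16. Of 250 probe sets that differed between the lines, 66.8% were further in the direction of DT40 in B41-13, those beyond the DT40 level included, and 68.8% were closer to that level. Chance drift of a single line cannot be told apart from an effect of kinase activity, because each construct was represented by 1 line and linked genes can drift together.

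In B7.10 the 616 probe sets called after 6 h of stimulation with the serum batch as a block were weighed by a score, the mean of risen minus that of fallen members. The score was higher by 1.01, 0.89 and 1.19 in the stimulated arrays of serum batches 1, 2 and 3 (mean 1.03), by construction of the set. With as many probe sets chosen in the other 2 batches it was higher by 0.49, 0.41 and 0.83 in serum batches 1, 2 and 3 (mean 0.58), with 80.2%, 82.6% and 95.8% of them in the same direction. Quality varying from array to array would move this score among unstimulated DT40 arrays as much. Its range there was 0.51, 0.35 and 0.29 (mean 0.38), so this remains open, and so does a quality difference shared by all unstimulated B7.10 arrays. With cyclic loess and the block 599 probe sets were called, which argues against array scaling. A response to stimulation without BTK may remain open, since the score was also higher in 5 of 5 pairs of the other lines (0.26, 0.50 and 0.41 in DT40, 0.35 in B41-13 and 0.44 in B46-5), against ranges of 0.37 and 0.50 over the unstimulated arrays of DT40 and B7.10. Of the 3 stimulated B7.10 arrays 2 have disputed labels. Without them the block fit had 1 stimulated array left, so it does not tell whether the labels are wrong.

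BASP1 was flagged because its 6 h response differed between the lines, by -2.21 log2. The lists of receptor signalling and ER stress (medians 0.07 and 0.07), fibroblast markers (median -0.13), S-phase genes and epithelial markers were flagged since their 6 h response differed between B7.10 and DT40 (camera adjusted p = 0.0229, 0.0229, 0.0229, 0.041 and 0.0414). No member passed limma in any of these 5 lists (5, 1, 3, 0 and 1 at an unadjusted p under 0.05), and adjusted over the list alone 1 epithelial marker was lower. All 5 calls ended with an estimated correlation (adjusted p = 0.689, 0.689, 0.4, 0.789 and 0.689) and with cyclic loess (0.27, 0.27, 0.27, 0.462 and 0.318). OSTN and MAT1A were flagged for a 24 h change that differed by 1.90 and 2.09 log2, though both lay near background in B7.10, where a fall may not be readable. The ATF4 and cholesterol lists were flagged for the same comparison at adjusted p = 0.00384 each (0.934 and 0.843 with an estimated correlation).

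Among data outside the comparisons, 1 of 57 reporter probe sets, RPTR-Gga-U57609-2_s_at, was 7.07 log2 higher on average in the 3 derived lines than in DT40. It read 3.50 ± 0.23 in DT40 (SD, n = 10 arrays), 10.54 ± 0.16 in B7.10 (n = 10), 10.53 ± 0.11 in B41-13 (n = 4) and 10.69 ± 0.35 in B46-5 (n = 4). What this probe set reads is not given in the sources used here.

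The samples were also split in other ways. Over 100 splits drawn at random for the mean difference of B7.10 from DT40, 1 split, the real one, gave 5157 calls and the highest other gave 1, so chance was excluded. The same held for serum batches (1 of 100 splits; 298, highest other 8). In serum batch 1, with 35 splits each, 1 split, the real one, gave the count in every comparison under free exchange of the arrays. The fit pairs arrays by condition or line, and with pairs kept there are 8 splits, too few for a share under 0.05 (highest other 0, or 2 for B41-13 against DT40). The real counts and highest others were 4173 and 2 for B7.10, 4929 and 2 for B41-13 and 4376 and 1 for B46-5 against DT40. They were 4130 and 0 for B41-13 and 2705 and 0 for B46-5 against B7.10, and 4244 and 1 for B41-13 against B46-5. For conditions they were 3056 and 1 (2 h against 6 h unstimulated), 5 and 1 (6 h stimulated), 361 and 1 (24 h) and 2747 and 1 (2 h against 6 h stimulated).

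With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest other were 1854 and 0 for B7.10 against DT40 at 6 h, 1705 and 39 at 24 h and 2071 and 0 with stimulation. They were 17 and 2 for the DT40 stimulation, 0 and 0 for that of B7.10 (all 10 splits equal), 220 and 0 for 24 h in DT40 and 89 and 10 in B7.10. Among the 4 splits that part as many pairs as the real one the highest other was 0 in each of these. For the difference in stimulation response 17 of 100 splits gave as many calls as the real 1, so chance was not excluded, and the highest other gave 400. For the difference in the 24 h change 12 of 100 did, with 2 real calls and 1166 in the highest other. Splits with several times the real count point to a structure of the samples. The one with 400 calls exchanged the stimulated and unstimulated labels of all 3 arrays per group in DT40, which tests the sum of both responses, and the one with 1166 exchanged the labels of 2 arrays per group in B7.10 and of 0 in DT40.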

How the results depend on the processing

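The fits without the arrays whose labels disagree, without both 24 h arrays of serum batch 3, of the kinase contrast and of the block without the disputed arrays were added after results had been seen, and the other alternatives were planned. Of the named single genes, 2686 recomputed values stayed on their side of the threshold, 258 lost a call and 22 gained one, and 0 called values reversed. Of the counts, slopes and lists, 207 moved by at most 1.5 times (slopes: by at most their SD over conditions) and 99 by more. No depth can be given for arrays, and probe sets with a mean under 3.98 log2 were taken as near background. Leaving them out moved no count by over 1.5 times.

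With the serum batch as a block calls were 41 for the DT40 stimulation and 616 for that of B7.10 (main fit 17 and 0). They were 2 for the difference in response, 554 for 24 h in DT40 and 270 in B7.10 (main fit 1, 220 and 89). For B7.10 against DT40 within conditions, the immediate-early list at 6 h (camera adjusted p = 0.0482, against 0.061) and the ribosome biogenesis, cholesterol and fatty-acid lists at 24 h (0.049 each, against 0.0578, 0.0758 and 0.0593) passed with the block, while calcium and NFAT genes with stimulation no longer did (0.0559, against 0.0454). Beyond these and the counts, genes and lists named with the comparisons, the replicate block changed no other call of a named gene or list and moved no other count by over 1.5 times. The serum batch 1 comparisons and the kinase contrast are already paired by line and condition in their fit, and the slopes were compared within conditions. A block by serum batch could not be added to them, because their arrays carry 1 batch number, nor to the serum batches, since the batch is the effect tested. The mean over 3 conditions uses all 18 arrays, so a fit of only the arrays compared was not run for it.

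With cyclic loess 1 probe set was called for the B7.10 stimulation and 14 for 6 h of stimulation in serum batch 1. With only the arrays compared, which leaves fewer degrees of freedom, B7.10 against DT40 at 24 h gave 728, the DT40 stimulation 6, the difference in response 0, 24 h in DT40 29 and in B7.10 4. In serum batch 1 this setting gave 0 for 6 h of stimulation and 613 for 24 h. Without both 24 h arrays of serum batch 3 the count was 892 for B7.10 against DT40 at 24 h, 333 for the B7.10 stimulation, 97 and 17 for 24 h in DT40 and B7.10, 0 for the difference in the 24 h change and 103 for serum batches. Without the B7.10 stimulated arrays whose labels disagree it was 958 for B7.10 against DT40 with stimulation, 0 for the difference in response, 146 and 25 for 24 h in DT40 and B7.10 and 1 for the difference in the 24 h change. Without the 3 arrays whose labels disagree in serum batch 1 it was 2500 for B46-5 against DT40, 1406 against B7.10, 2190 for B41-13 against B46-5, 0 for 6 h of stimulation, 118 for 24 h and 970 for 2 h against 6 h stimulated. Fits that leave out arrays test fewer samples, and for the other settings the cause was not tested.

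The slope of B41-13 was 0.341 as a median ratio. That of B46-5 was 0.165 as a median ratio and 0.248 with no fold minimum. Of 112 list calls 8 were left with an estimated correlation, 124 were made with fry, 125 with the mean of all probe sets of a gene, 104 with cyclic loess, 92 without dim probe sets and 106 without both 24 h arrays of serum batch 3. The 101 calls of the kinase contrast became 98 with cyclic loess, 93 without dim probe sets and 148 with trend and robust moderation.

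Leaving out each array or batch in turn gave counts from 3083 to 4149 for the mean of B7.10 against DT40, 1099 to 1642 at 6 h, 968 to 2380 at 24 h and 1261 to 1921 with stimulation. They were 5 to 38 for the DT40 stimulation, 0 to 74 for that of B7.10, 0 to 12 for the difference, 69 to 1341 for 24 h in DT40, 9 to 290 in B7.10, 1 to 2 for the difference in the 24 h change and 57 to 236 for serum batches. In serum batch 1 they were 3468 to 3802, 3782 to 4397 and 3309 to 3887 for B7.10, B41-13 and B46-5 against DT40, 3082 to 3945 and 2114 to 2375 for B41-13 and B46-5 against B7.10, and 3390 to 3640 for B41-13 against B46-5. For conditions they were 1754 to 2598 (2 h against 6 h unstimulated), 0 to 6 (6 h stimulated), 104 to 232 (24 h) and 1847 to 2522 (2 h against 6 h stimulated). Leaving out each condition gave slopes of 0.388 to 0.423 for B41-13 and 0.228 to 0.231 for B46-5.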

Other observations

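In serum batch 1 hypoxia genes were lower than in DT40 in all 3 derived lines, and glycolysis genes in B41-13 and B46-5. These comparisons share the DT40 arrays, so likenesses between the lines partly share chance values. Of 27 hypoxia-inducible genes 9 were lower and 2 higher in B7.10, 11 lower in B41-13, and 10 lower and 1 higher in B46-5 (9 and 2, 13, and 14 and 2 adjusted over the list alone; camera adjusted p = 0.00591, 0.000834 and 0.00214, and 0.264, 0.0982 and 0.329 with an estimated correlation). Of 21 glycolysis genes 7 were lower in B41-13 and 6 in B46-5 (11 and 9 adjusted over the list alone; adjusted p = 0.00643 and 0.00203, and 0.474 and 0.334 with an estimated correlation). In B7.10 4 were lower and 1 higher (6 and 1 adjusted over the list alone; adjusted p = 0.161). Over 3 batches neither list passed (adjusted p = 0.213 for both). In that mean of B7.10 against DT40 the hypoxia regulator HIF1A was lower at -0.72 ± 0.12 log2 (SE, 3 arrays in each of 6 groups; limma, Benjamini-Hochberg adjusted p = 0.000174), PFKP at -0.43 ± 0.05 and ENO2 at -0.47 ± 0.08, while KDM3A was higher by 0.31 ± 0.06 and, on 1 of its 2 probe sets, ERO1A by 0.43 ± 0.06. BHLHE40 was lower at -0.81 ± 0.08, but another of its 4 probe sets was higher by 0.16. In serum batch 1 B-cell identity genes were higher than in DT40 in all 3 lines, with 11 of 39 higher and 2 lower in B7.10, 17 and 4 in B41-13 and 12 and 4 in B46-5 (15 and 2, 18 and 4, and 12 and 4 adjusted over the list alone; camera adjusted p = 0.000832, 3.55e-05 and 0.0459, and 0.264, 0.09 and 0.337 with an estimated correlation). This likeness too comes from comparisons that share the DT40 arrays.

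Among genes usually read as markers of other blood cells, the myeloid transcription factor SPI1 was higher in B7.10 by 0.47 ± 0.07 log2 and TLR2A by 0.72 ± 0.11. The integrin subunit ITGA3 was higher by 0.45 ± 0.06 and the tetraspanin CD151 by 0.38 ± 0.06. The difference in PTPRG was -5.01, -2.99 and -5.35 in serum batches 1, 2 and 3, and that in CYBB was -4.01, -2.02 and -3.43, both smaller in batch 2, where BTK differed by -5.10.

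Over the probe sets chosen for the return towards DT40, B41-13 covered over 50% of the difference at 167 of 419 (39.9%) and B46-5 at 114 (27.2%), with 67 in both lines. In the direction away from DT40 lay 74 in B41-13 and 130 in B46-5. The median share covered was 0.361 and 0.155. Measured against a set of probe sets chosen in the other lines, the 2 h response had a slope of 0.92 in DT40, 0.65 in B7.10, 1.03 in B41-13 and 0.59 in B46-5, and 91.0% of the probe sets had the same direction in DT40 and more in each other line. Principal components of the 28 arrays held 28.5%, 13.6%, 11.5% and 9.21% of the variance. Of 118 called gene values with other probe sets on the array, 85 had another called in the same direction, 1 in the opposite direction, and 32 had no other called.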
